A study of Saccharomyces cerevisiae with 4 samples.

How the data were processed

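The material is chromatin immunoprecipitation followed by sequencing (ChIP-seq) of Swc4 in budding yeast, Saccharomyces cerevisiae. Per the labels' protocols, haploid cells of the BY laboratory background were grown without treatment in rich medium to mid-log phase, chromatin was sonicated, and DNA was precipitated with an antibody against the myc tag. Swc4 carried 13 copies of that tag in all 4 libraries. The labels give 2 genotypes with 2 libraries each. One is wild_type, the other is yaf9d, in which the sample titles name a deletion of YAF9. The genotype entry of the yaf9d samples repeats the tag alone, so the group of every sample was taken from its title. The labels do not say whether the 2 libraries of a genotype came from separate cultures, and the spread between them may be technical.

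The authors deposited 1 peak list per library, called on that library and not on pooled reads. Per the submitters' processing notes, BWA 0.7.15-r1140, SAMtools 1.4 and MACS2 (version given as 2) were used. The roles of these tools, the genome build, the control sample, the treatment of reads with several matches and the peak threshold are not given in the sources used here. Each deposited list gives the interval and summit of a peak, a score, a ratio and 2 probabilities. The ratio is the authors' fold enrichment at the summit over a local background. Whether that background came from the same library or from a control is not stated. The authors' probabilities are a −log10 p-value and a −log10 q-value at the summit, and the lowest listed −log10 q-value was 1.31. The deposited score equalled 10 times the −log10 q-value with decimals dropped in 3382 of 3382 peaks, and was not used further. A fold or q-value of a peak was used to describe, rank or filter peaks within its own list, and folds were not tested between lists.

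No read totals come with the lists. Depth was read from the peaks themselves. The fold was taken as the summit pileup plus 1 divided by the background plus 1, and the p-value as the upper tail of a Poisson distribution. The whole-number pileup that gave the listed −log10 p-value within 0.001 was then searched for each peak. Such a pileup was found for 99.5% of peaks in wild_type replicate 1, 99.9% in wild_type replicate 2, 99.7% in yaf9d replicate 1 and 99.5% in yaf9d replicate 2. These pileups are on the scale the caller used, which may be scaled to a control. Binomial intervals below cover counting error only.

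Peak starts are printed 1-based. Gene names and neighbourhoods came from a RefSeq gene table of assembly R64. Strand was read from the last letters of the systematic name, which was missing for 1 nuclear gene. The table holds 6477 genes, and 0 members of the gene lists were without a match. Since the build of the lists is not named, coordinates of that table are not printed. As a check, summits within 300 bp of the middle of a tRNA gene were compared with that middle. Of 298 such summits, 88.3% lay within 100 bp, and the median offset per chromosome ranged from -12 to 45.5 bp. Chromosome lengths were not given and were taken as the outermost gene or peak end. Centromeres, replication origins and long terminal repeats, planned as classes, have no rows in that table and are not analysed here.

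Peaks on the 16 nuclear chromosomes were used for all comparisons. Overlap meant 1 bp or more. Jaccard indices are shared over united base pairs, set beside random placements of peaks on their own chromosomes. Peaks of the 4 libraries were merged into loci wherever they overlapped, and each locus was given the libraries that called it. A feature counted as covered when a peak overlapped it. Each of 7 feature classes was tested per library against 1000 random placements, one-sided, with Benjamini-Hochberg adjustment over 28 class-by-library tests. A promoter was the 500 bp upstream of a coding start. The 10 gene lists, fixed before the data were examined, hold ribosomal proteins, glycolysis and fermentation, translation factors, ribosome biogenesis, heat shock proteins and chaperones, histones, subunits of the SWR1, NuA4 and INO80 complexes, DNA repair and checkpoint, chromosome segregation, and telomere maintenance and silencing. Members were compared with all other nuclear protein-coding genes by Fisher's exact test, two-sided, adjusted over 60 list-by-set tests (4 libraries, and loci called in both libraries of each genotype). Genes are not independent replicates, and these tests describe a library, not a genotype. Genotypes were compared by an exact two-sided permutation test of the 4 library values. With 2 against 2 its smallest p is 0.333, so this test could not pass 0.05 for any genotype difference, and no other genotype test was run.

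Named loci followed a rule fixed in advance. It takes the 10 loci per genotype with the best mean rank of fold within each list, the 10 best loci of each difference pattern, up to 3 members of each list or class, and YAF9 and SWC4. Items named outside it are marked as chosen after their values were seen. Other settings chosen before the data were examined were a −log10 q of 5 or more, a fold of 2 or more, the same number of peaks in each library (616, the shortest list, by q-value), summits with 100 bp on each side, overlap of 50% of both peaks, wider promoters, gene bodies, wider tRNA genes, leaving out genes near tRNA genes, pairing by replicate number, and leaving out each library. Differences that carry only a test of libraries are named as such. The 39 peaks on the mitochondrial genome were left out of every comparison.

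Analysis used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9. The procedures were tested on simulated peak lists before use. Of 60 tRNA genes planted under 700 peaks, 60 were recovered, and 4 of 100 random lists gave p under 0.05 for that class. With 70 ribosomal protein promoters planted, that list was called and 0 others were. Of 40 loci planted in wild_type alone, 40 were found, and 500 of 500 simulated pileups were recovered.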

Results

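Swc4 is a subunit shared by the SWR1 chromatin remodeler, which exchanges histone H2A for the variant H2A.Z, and the NuA4 histone acetyltransferase. Yaf9, a YEATS-domain protein that binds acylated histone H3, is also shared by both complexes. The series, which concerns Swc4 in genome stability and aneuploidy, maps tagged Swc4 along the genome in wild_type cells and in cells lacking YAF9. Each genotype has 2 libraries. The files hold the peaks of each library, so a locus without a peak is one that was not called, and it is not shown to be unbound.

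Nuclear peaks numbered 884 and 704 in wild_type replicates 1 and 2, and 616 and 1139 in yaf9d replicates 1 and 2. They covered 464, 512, 313 and 555 kb in the same order. The mean was 794 ± 127 peaks in wild_type and 878 ± 370 in yaf9d (SD, n = 2 each; exact two-sided permutation p = 1), a difference smaller than the spread between replicates. The median fold enrichment given by the authors was 1.83, 1.92, 2.50 and 1.81. Summit pileups recovered from the lists had medians of 131.5, 126, 132 and 146, over median backgrounds of 64.5, 56.2, 46.5 and 71.3. The share of peaks with a fold of 2 or more was 37.0%, 44.6%, 66.9% and 37.0%. Median peak widths were 447.5, 611.5, 438 and 407 bp.

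Ribosomal protein genes held most of the best-ranked Swc4 loci in both genotypes. Of the 10 loci with the best mean rank, 9 in wild_type and 8 in yaf9d overlapped the promoter of a gene for a ribosomal protein. The first in either genotype lay on chromosome II from 332324 to 333026, over RPS11B, with folds of 6.42, 9.03, 14.0 and 7.23 in wild_type replicates 1 and 2 and yaf9d replicates 1 and 2. The divergent pair RPL13B and RPS16A shared a peak on chromosome XIII from 551146 to 552102 with folds of 5.08, 8.58, 12.2 and 7.89. RPS23A, RPS0B, RPL41B, RPL42B, RPL6B, RPL6A and RPS18A completed the ribosomal set in wild_type. RPL31A, RPL24B and RPS23B entered the first 10 in yaf9d.

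The exceptions among the best loci were few. One was a subtelomeric peak on chromosome XII from 5423 to 5946, over the small open reading frame YLL066W-B, with folds of 9.44, 6.54, 6.01 and 5.99, and it was the highest fold in wild_type replicate 1. In yaf9d, the first 10 also held a peak at GAL3 and SNQ2 (chromosome IV, 464746 to 465597), with folds of 12.1 and 7.45 against 4.36 and 3.28 in wild_type. Another lay at ENV9 and SRL1 (chromosome XV, 796569 to 797354), with 10.9 and 9.16 against 5.08 and 4.51, and it was the highest fold in yaf9d replicate 2. Folds belong to their own list and were not tested between genotypes.

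The 137 ribosomal protein genes were tested as a list, asking whether Swc4 favours this group in each library. A promoter peak was present at 87 and 97 of them in wild_type and at 85 and 83 in yaf9d, against 14.7%, 13.0%, 10.1% and 12.5% of other protein-coding genes. The odds ratios were 10.1, 16.2, 14.6 and 10.8 (Fisher's exact test, adjusted p of 2.7e-36, 1.1e-50, 2.3e-46 and 1.3e-37). Promoters of 76 had a peak in all 4 libraries, and 35 had none in any library. The genotype means were 92 ± 7.07 and 84 ± 1.41 (SD, n = 2; exact permutation p = 0.333, the smallest possible). With peaks of fold 2 or more, yaf9d exceeded wild_type by 3.5 genes, and with summit windows by 5.5, so no direction is given for this difference. Summit windows left 67 and 65 genes in wild_type and 73 and 70 in yaf9d. RPL4A, RPL4B, RPL14B and RPP1A, named after their values were seen, had a promoter peak in both wild_type libraries and neither yaf9d library. The reverse held for 0 genes of the list. Merged loci called in both wild_type libraries and neither yaf9d library touched 2 promoters of the list, 1.46% against 3.05% of other genes. Not all 4 of the named genes thus lay at loci without a yaf9d call.

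At these genes the nearest summit most often lay 200 to 300 bp upstream of the coding start. The nearest summit within 1 kb lay at a median of 210 and 184 bp upstream in wild_type (102 and 117 genes) and 232.5 and 215.5 bp upstream in yaf9d (94 and 110 genes). It was upstream in 67.6%, 57.3%, 84.0% and 67.3% of these genes, against 54.0%, 60.1%, 75.8% and 56.8% of all protein-coding genes with a summit within 1 kb, so the share was below that of all genes in wild_type replicate 2. Bins from 200 to 300 bp upstream held 39, 36, 46 and 41 genes.

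**Figure D1:**
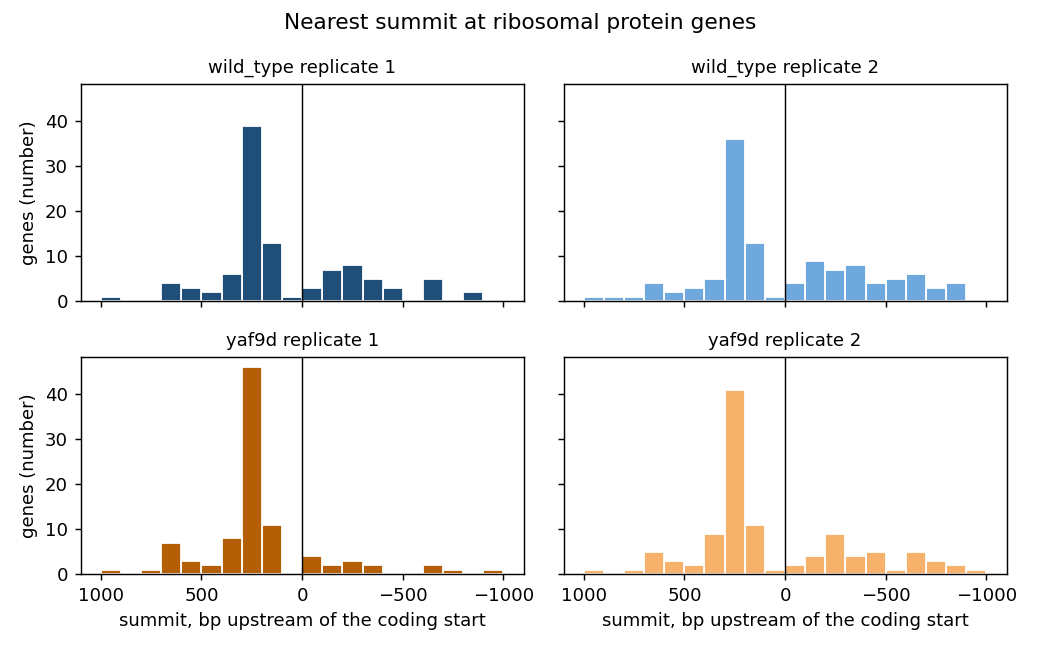
Distance from the coding start of each ribosomal protein gene to the nearest peak summit, in bins of 100 bp. Positive values are upstream and negative values downstream of the coding start. Bars give the number of genes, and in each library the bin from 200 to 300 bp upstream is the highest, with 39, 36, 46 and 41 genes.

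No other gene list passed the test in all libraries. Histone genes passed in wild_type replicate 2, with a promoter peak at 7 of 10 (odds ratio 14.1, Fisher's exact test, adjusted p = 0.00083). They also passed in loci called in both wild_type libraries, with 5 of 10 promoters touched (Fisher's exact test, adjusted p = 0.024). Loci merge the peaks of all libraries, so a locus can touch a promoter that the peak of a given library does not. A promoter peak in each of the 2 wild_type libraries was present at 3 of 10. In each of the other 3 libraries 3 of 10 had one, and that call is not shared by them. With peaks of fold 2 or more the call was lost, with 2 of 10 in wild_type replicate 2 (exact adjusted p = 0.94) and 0 of 10 in loci of both wild_type libraries, and gene bodies gave exact adjusted p = 0.070 and 0.17. HHT2 and HHF2, the divergent histone H3 and H4 genes, and HTZ1, the H2A.Z gene, had a promoter peak in all 4 libraries, with folds between 1.37 and 1.72. Translation factors had 7 of 18 members with a promoter peak in each wild_type library (Fisher's exact test, adjusted p = 0.095 and 0.060) and 5 of 18 in each yaf9d library (adjusted p = 0.22 and 0.32), which does not pass. At a −log10 q of 5 or more the list passed in wild_type replicate 2 with 7 of 18 (exact adjusted p = 0.017). TEF1, HYP2 and EFT2 had a peak in all 4 libraries. HYP2, which encodes translation factor eIF5A, lay at a merged locus on chromosome V from 85043 to 86717. The highest folds of each library there were 1.44 and 2.14 in wild_type and 6.45 and 5.63 in yaf9d. These peaks need not share a summit, so the folds may belong to different sites.

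Lists tied to the subject of the series did not pass the test. Of 29 DNA repair and checkpoint genes, 5 and 5 had a promoter peak in wild_type and 7 and 7 in yaf9d, and the lowest adjusted p was 0.21 (yaf9d replicate 1). MEC1, the checkpoint kinase, RNR2, a ribonucleotide reductase subunit, and RMI1, a partner of the Sgs1 helicase, had a promoter peak in all 4 libraries, with RNR2 folds of 2.26, 2.48, 3.24 and 2.72. Of 30 chromosome segregation genes, 4 and 3 had one in wild_type and 1 and 2 in yaf9d, with adjusted p from 0.53 to 1. SGO1, the shugoshin that guards centromeric cohesion, had one in all 4 libraries with folds of 2.85, 2.85, 3.26 and 4.27. Among kinetochore genes, SPC25 was the one with a promoter peak in both wild_type libraries and neither yaf9d library, though its locus on chromosome V from 191569 to 192695 was also called in yaf9d replicate 2 (fold 1.45). The locus at DSN1 on chromosome IX from 375293 to 375841 had folds of 2.41 and 2.23 in wild_type and was not called in yaf9d, though another peak touched the DSN1 promoter in yaf9d replicate 2. Of 15 telomere maintenance and silencing genes, 2 and 1 in wild_type and 0 and 0 in yaf9d had a promoter peak, and EST3, a telomerase subunit, was called in both wild_type libraries alone. Ribosome biogenesis, glycolysis, chaperone and remodeler subunit lists did not pass in any library either, with UTP22, HXK2, HSP42 and SWR1 as their best-ranked members.

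Transfer RNA genes were covered more often in yaf9d than in wild_type, and in each library far more often than random placement gives. Of 275 nuclear tRNA genes, short genes transcribed by RNA polymerase III, 55 and 71 lay under a peak in wild_type and 94 and 102 in yaf9d. Random placement gave means of 12, 13.0, 8.14 and 14.4 (permutation of peak positions, adjusted p = 0.00311 in each library, the smallest these placements and this adjustment give). The means were 63 ± 11.3 and 98 ± 5.66 genes (SD, n = 2). The difference of 35 genes exceeded the spread between replicates, and each yaf9d library lay above each wild_type library (exact two-sided permutation p = 0.333, the smallest possible). In all 4 libraries 35 tRNA genes had a peak. A further 26 had one in both yaf9d libraries and neither wild_type library, against 4 in the reverse pattern. SUF8 on chromosome VIII (peak from 388724 to 389155) had folds of 3.13, 3.85, 5.24 and 5.01, and the neighbours YNCB0015W and YNCB0016W on chromosome II (405748 to 406219) had 2.86, 3.54, 5.19 and 4.86. Many tRNA genes have near-identical copies, and how the authors' processing placed reads shared between copies is not stated.

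**Figure D2:**
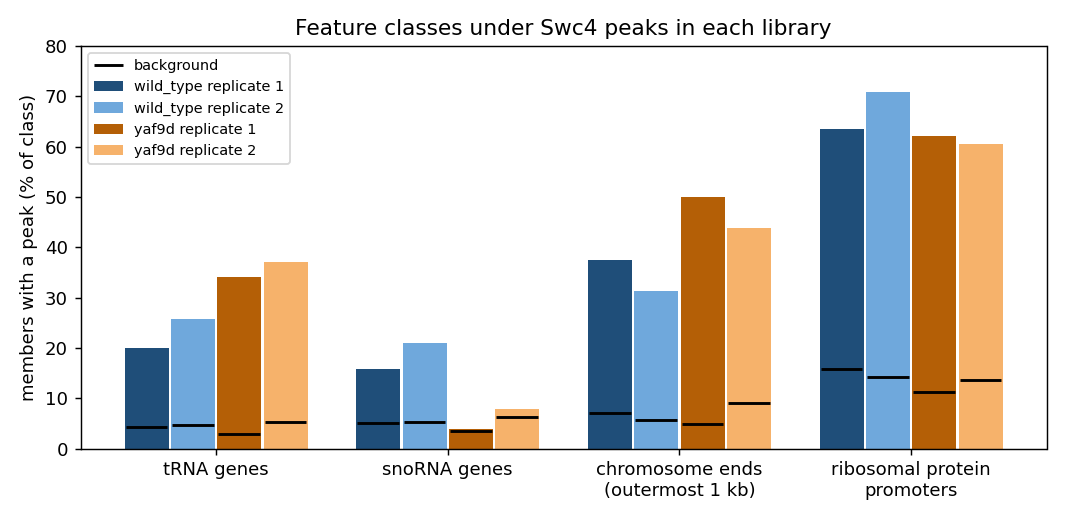
Percent of tRNA genes, snoRNA genes, chromosome ends and ribosomal protein promoters with a peak, 1 bar per library. Black lines give the mean of 1000 random placements for the first 3 classes and the share of all protein-coding promoters for the last. For tRNA genes the yaf9d bars stand at 34.2% and 37.1% and the wild_type bars at 20% and 25.8%.

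Genes for small nucleolar RNAs (snoRNAs), which guide modification of ribosomal RNA, went the other way. Of 76 such genes, 12 and 16 were under a peak in wild_type (permutation of peak positions, adjusted p = 0.0056 and 0.0031) and 3 and 6 in yaf9d (adjusted p = 0.57 and 0.45). The means were 14 ± 2.83 and 4.5 ± 2.12 (SD, n = 2; exact permutation p = 0.333, the smallest possible). Both wild_type libraries had a peak at 10 of these genes. Of the 10, SNR11, SNR53 and SNR58, named after their values were seen, had none in yaf9d. The others had a peak in at least 1 yaf9d library, and 1 had it in all 4 libraries. A peak in both yaf9d libraries and neither wild_type library was present at 0 genes. With summit windows the yaf9d minus wild_type difference moved from -9.5 to -4 genes.

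Other genes of polymerase III had peaks in both genotypes, with 3 of 5 covered in 3 libraries and 2 of 5 in yaf9d replicate 2 (permutation of peak positions, adjusted p = 0.0086, 0.0076, 0.0086 and 0.13). SCR1, the RNA of the signal recognition particle, had folds of 2.64, 3.42, 4.91 and 3.97, and RPR1, the RNA of ribonuclease P, had 2.38, 2.97, 3.57 and 2.91. Repeated 5S genes of the ribosomal DNA did not make the rRNA class pass in any library (same permutation test, lowest adjusted p = 0.13). Of 32 chromosome ends, 12 and 10 in wild_type and 16 and 14 in yaf9d had a peak in the outermost 1 kb (permutation of peak positions, adjusted p = 0.0031 in each library). The means were 11 ± 1.41 and 15 ± 1.41 (SD, n = 2, exact permutation p = 0.333). Each right end was placed at the outermost gene or peak end over all lists. Where a peak set it, that end counted as covered by construction. Neither the random placements nor the comparison of means allows for this. The right end of chromosome VIII had a peak in all 4 libraries, from 562124 to 562631, with folds of 3.87, 6.18, 5.75 and 5.53. Subtelomeric repeats are also nearly identical between ends. In the outermost 20 kb the number of ends with a peak did not pass in any library (permutation of peak positions, adjusted p from 0.056 to 0.96), though at a −log10 q of 5 or more it passed in yaf9d replicate 1 (25 of 32, adjusted p = 0.0086). It passed in all 4 with peaks of fold 2 or more, a setting added after the data were seen. The 6 spliceosomal snRNA genes did not pass either.

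Across the genome, summits lay in promoters for 31.8% and 32.8% of wild_type peaks and 39.4% and 23.9% of yaf9d peaks, against 21.0% to 21.1% at random (permutation of peak positions, one-sided p = 0.000999, the smallest possible, in 3 libraries and 0.011 in yaf9d replicate 2). RNA genes held 4.64%, 6.68%, 12.01% and 7.55% of summits, against 0.70% to 0.75% at random. Coding sequences held 55.8%, 47.9%, 29.2% and 59.96%, below the 67.3% to 67.5% of random summits.

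Peak sets of the same genotype overlapped more than sets of different genotypes. The Jaccard index was 0.353 between the wild_type libraries and 0.333 between the yaf9d libraries. The 4 pairs across genotypes gave 0.240, 0.252, 0.266 and 0.266, and random placement at most 0.0311. The mean within genotypes exceeded that between them by 0.0869. Pairing the libraries in the other ways gave differences of -0.0481 and -0.0388. With 3 ways of pairing 4 libraries, a share under 0.05 cannot be reached.

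Merging gave 1726 loci, of which 251 were called in all 4 libraries and 892 (51.7%) in 1 library alone. Of those 892, 446 came from yaf9d replicate 2 and 251 from wild_type replicate 1. Of 475 loci called in both wild_type libraries, 353 (74.3%, exact 95% interval 70.1 to 78.2) were called in at least 1 yaf9d library and 251 (52.8%) in both. Of 463 loci called in both yaf9d libraries, 361 (78.0%, 73.9 to 81.7) were called in at least 1 wild_type library. Both wild_type libraries and neither yaf9d library called 122 loci, and 102 showed the reverse. Those 224 loci compare with 72 and 75 for the other ways of pairing. With a fold of 2 or more, 35 and 88 loci were left in these patterns. Leaving out 1 library lets the other stand for its genotype. The wild_type pattern then numbered 225 without wild_type replicate 1, 390 without wild_type replicate 2 and 206 without yaf9d replicate 2. The yaf9d pattern numbered 168 without wild_type replicate 2, 550 without yaf9d replicate 1 and 195 without yaf9d replicate 2.

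**Figure D3:**
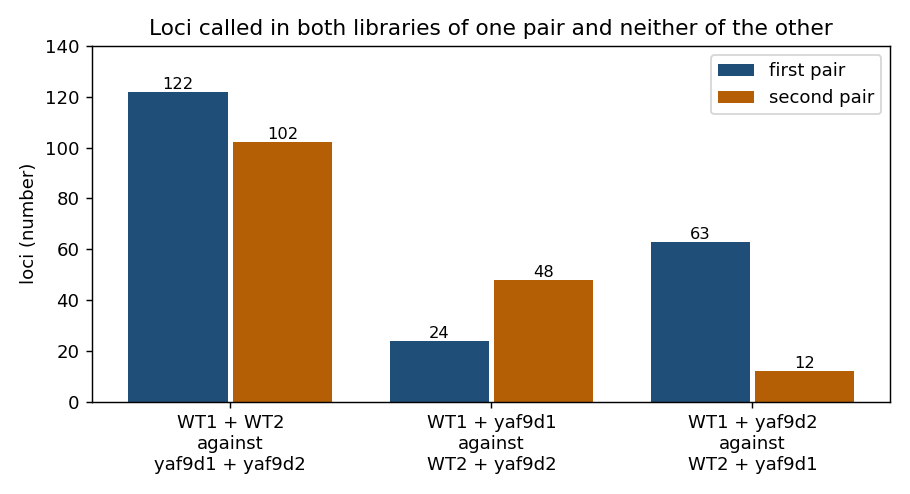
Number of loci called in both libraries of 1 pair and neither library of the other, for the 3 ways of splitting the 4 libraries into pairs (WT, wild_type). The split by genotype gives 122 and 102 loci, and the other splits give 24 and 48, and 63 and 12.

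The best-ranked locus called in wild_type alone lay at the promoter of SWR1. SWR1, the ATPase of the remodeler that Swc4 belongs to, had a peak on chromosome IV from 1135653 to 1136341 with folds of 3.49 and 3.07. RRP7 (chromosome III, 65067 to 66186; 3.45 and 2.81), BMS1 (chromosome XVI, 142777 to 143292; 3.44 and 2.58) and UTP9 (chromosome VIII, 491772 to 492165; 2.92 and 2.73) act in processing of the small ribosomal subunit, but the ribosome biogenesis list had 0 of 27 members under the 122 loci. The others were at ZRT1, the high-affinity zinc transporter, and FZF1, GCS1, FUN12 with RBG1, TOM6, OST5, and SRP54, with folds from 2.26 to 3.15. Loci called in 1 genotype alone ranked lower than those called in all 4 libraries. The median rank of the 122 was at 52.6% of the wild_type lists (0% strongest) against 25.2% for shared loci, and that of the 102 yaf9d loci at 42.2% of the yaf9d lists against 21.7%.

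The best-ranked loci called in yaf9d alone included those at BTN2 and HSP42 and at 3 tRNA genes. BTN2, which sorts misfolded proteins, had a peak on chromosome VII from 771574 to 772371 with folds of 9.53 and 4.50. HSP42, a small heat shock protein, had one on chromosome IV from 806125 to 807353 with 6.68 and 3.68. HSP42 was the 1 of 19 heat shock and chaperone genes with its promoter under such a locus (Fisher's exact test, adjusted p = 1). ISA1, an iron-sulfur assembly gene, had one on chromosome XII from 86832 to 87215 with 5.90 and 4.43. A peak over the promoters of CCW12 and HOG1 (chromosome XII, 370478 to 371364) had folds of 3.78 and 3.94. The tRNA genes were YNCE0018W (3.75 and 3.89), YNCD0024C (3.78 and 3.58) and YNCG0036W (4.19 and 3.01). The rest lay beside YAF9, on chromosome IX from 386536 to 386958, and at the right end of chromosome XIV from 783472 to 784318.

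The 2 sets of differing loci held unlike shares of tRNA genes and promoters. A tRNA gene lay under 26 of the 102 loci called in yaf9d alone (25.5%) and under 4 of the 122 called in wild_type alone (3.28%). Fisher's exact test gave p = 8.3e-07, which compares these libraries and not the genotypes. It was chosen after the data were seen and draws on the same peaks as the tRNA gene counts above, so it is not separate support. The other ways of pairing gave exact p = 0.41 and 1. Without yaf9d replicate 1, where loci of yaf9d replicate 2 stand for the genotype, 550 loci showed the yaf9d pattern and the shares differed by 1.53 percentage points (exact p = 0.68), while the tRNA gene difference was 39. Promoters lay under 86.1% of the loci called in wild_type alone and 63.7% of those called in yaf9d alone (Fisher's exact p = 0.00014). The mean of the median peak widths was 529.5 bp in wild_type and 422.5 bp in yaf9d. Wider peaks can touch a promoter more often, and the comparison does not allow for width. None of the 10 gene lists passed among either set.

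YAF9 and SWC4 were looked up in each library. No library had a peak on either gene or on the SWC4 promoter. Both yaf9d libraries had a peak that began 1 bp beyond the end of the YAF9 coding sequence on chromosome XIV, at 420779, with folds of 4.88 and 4.66 and summits at 420794 and 420798. A further peak in yaf9d replicate 2, from 419589 to 419844 (fold 2.31), lay on the promoter side, 254 bp from the gene. Neither wild_type library had a peak within 1 kb of YAF9.

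Peaks differed in the background they stood on. For peaks with their summit in a ribosomal protein promoter (58, 56, 64 and 60) the median background was 0.637, 0.663, 0.775 and 0.665 times the library median, and the median fold was 3.99, 5.78, 8.13 and 5.13. Peaks inside glycolysis genes, which are transcribed at very high levels, numbered 9, 7, 2 and 9, with a median background 8.58, 7.71, 13.0 and 7.48 times the library median. Their median folds were 1.47, 1.19, 1.23 and 1.25, and 0 of the 27 reached a fold of 2. Peaks inside ribosomal protein genes (53, 61, 18 and 57) lay between, with a median background 3.32, 2.72, 3.92 and 2.91 times the library median and median folds of 1.63, 1.75, 1.44 and 1.82. Of these, 32, 25, 16 and 27 stood on a background over 3 times the library median, and 8, 14, 0 and 14 reached a fold of 2. PDC1 had the highest background in 3 libraries, with folds of 1.20, 1.17 and 1.14, and the one at place 3 in yaf9d replicate 2, with 1.46. PDC1 was named after its values were seen.

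**Figure D4:**
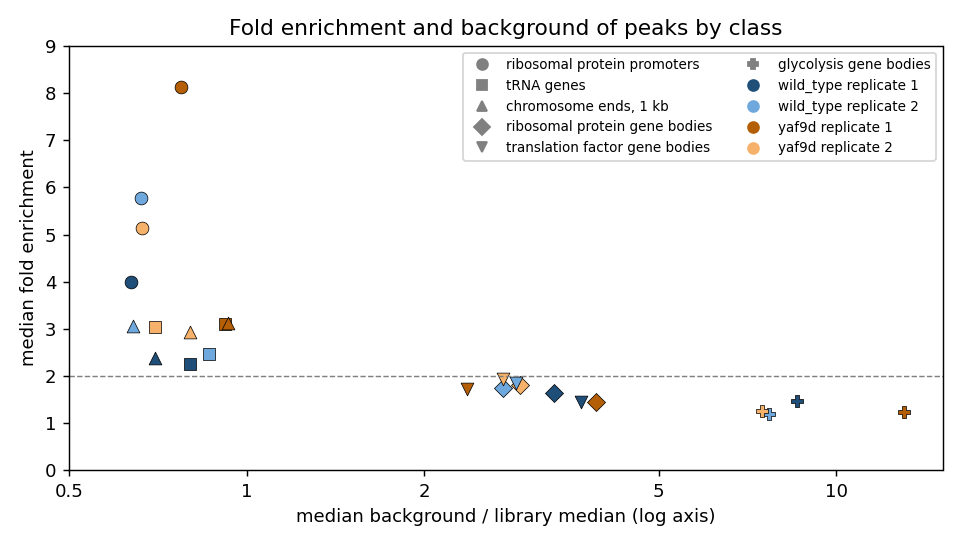
Median fold enrichment against median background relative to the library median (log axis) for peaks in 6 classes, 1 point per class and library; the dashed line marks a fold of 2. Ribosomal protein promoters sit at the upper left with folds from 3.99 to 8.13, and glycolysis gene bodies at the lower right with folds from 1.19 to 1.47.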

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

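Peaks on the mitochondrial genome were listed for 1 library and lie outside the nuclear comparisons. The library yaf9d replicate 2 had 39, covering 18.0 kb, with a median fold of 1.85 and a highest fold of 2.37. The other 3 libraries had 0. Mitochondrial DNA carries no nuclear chromatin, and no explanation was tested for these peaks. That library also had the longest nuclear list, with 1139 peaks, and the most loci called nowhere else, 446.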

How the results depend on the processing

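Differences in ribosomal protein, snoRNA and chromosome-end counts, the tRNA share of differing loci, other settings for yaf9d loci found in wild_type, and the fold minimum for classes and lists were examined only after the data were seen. Of 107 values under other settings, 73 kept their call or stayed within the spread between replicates (counts: within 1.5 times). This tally says little for the difference in peak number, which is 0 by construction with equal numbers of peaks. Its spread of 277 peaks let values from -178 to 345 count as kept, against 83.5 in the full lists. The tRNA difference of 35 genes was above 0 in 9 of 9 settings, the snoRNA difference below 0 in 8 of 8 and the chromosome-end difference above 0 in 8 of 8. Chromosome ends were set from the full lists in each of these settings. The ribosomal protein list passed in 24 of 24 tests on promoters under other settings, with odds ratios from 7.404 to 25.02. On gene bodies odds ratios ranged from 6.06 to 41.5. There any overlap with the gene counted, and part of the peaks inside these genes stood on a high background. With 2 libraries per genotype the exact permutation test cannot pass 0.05 under any setting, and weak loci missing from a list may lie just under its threshold: at a fold of 2 the loci called in both wild_type libraries alone fell to 35.

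With a fold of 2 or more, the within-minus-between Jaccard difference was 0.101, retention of reproducible wild_type loci in yaf9d 81.5% and of yaf9d loci in wild_type 70.1%. The tRNA difference was 45.5 genes, the ribosomal protein difference 3.5 against -8, and the snoRNA difference -6.5. Class tests other than those of tRNA genes that passed rose from 9 to 15, adding rRNA genes and other polymerase III genes in yaf9d replicate 2 and the outermost 20 kb in all 4 libraries. With equal numbers of peaks, the Jaccard difference was 0.109 and wild_type retention 69.9%. With summit windows they were 0.0652 for Jaccard, 71.8% for yaf9d retention, 5.5 genes for ribosomal proteins and -4 for snoRNAs. Overlap of 50% of both peaks gave retention of 67.7% and 71.3%. Gene bodies in place of promoters raised the list tests passed from 8 to 18. A promoter of 1000 bp raised the mean share of summits in promoters from 32.0% to 63.2%, which the wider window brings by itself. For the others the cause was not tested.

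Leaving out each library gave Jaccard differences from 0.0668 to 0.0997, 140 to 390 loci of the wild_type pattern, 148 to 550 of the yaf9d pattern, wild_type retention from 55.7% to 70.5% and yaf9d retention from 50.2% to 68.0%, since 1 library then stands for its genotype. The tRNA share of yaf9d minus wild_type differing loci ranged from 1.53 to 23.1 percentage points, and failed the exact test without yaf9d replicate 1 alone (p = 0.68).

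Replicate numbers are shared between genotypes, but the labels do not say that they mark a shared day. Across genotypes, libraries of the same number had Jaccard indices of 0.240 and 0.266, against 0.252 and 0.266 for libraries of different numbers. With the replicate block (same-numbered pairs alone between genotypes), the Jaccard difference was 0.090, and 51.0% of wild_type peaks were overlapped in yaf9d against 50.5% over all pairs.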

Other observations

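Heat shock and chaperone genes were overlapped by a peak more often in yaf9d, where gene bodies had been planned as an alternative to promoters. Any overlap of 1 bp or more with the gene counted, wherever the summit lay, and the HSP42 peaks also reached the HSP42 promoter. Of 19 such genes, 2 and 2 had a peak in the gene body in wild_type (adjusted p = 1 in both) and 7 and 8 in yaf9d (Fisher's exact test, adjusted p = 0.00049 and 0.012). The means were 2 ± 0 and 7.5 ± 0.707 (SD, n = 2; exact permutation p = 0.333, the smallest possible). The wild_type members were SSB1 and SSB2, the ribosome-associated Hsp70 genes. HSP42, HSP60, SSA1, SSA2 and SSC1, named after their values were seen, had one in both yaf9d libraries and neither wild_type library. The SSC1 locus on chromosome X from 520982 to 522174 was, however, also called in wild_type replicate 2 (fold 1.35) outside the gene, and the HSP60 peaks of the 2 yaf9d libraries did not overlap. HSP42 had folds of 6.68 and 3.68. SSA1 and SSA2, the main cytosolic Hsp70 genes, had 1.41 and 1.51 in yaf9d replicate 1, and SSA2 had 1.64 in yaf9d replicate 2. SSA1 had 3 peaks in yaf9d replicate 2, with folds of 1.62, 2.04 and 2.17 on backgrounds of 1.82, 0.832 and 1.147 times the library median.

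Translation factors passed as a list in gene bodies with 11 and 10 of 18 members in wild_type and 11 in yaf9d replicate 2 (Fisher's exact test, adjusted p = 2.8e-05, 6.1e-05 and 4.8e-05), but not in yaf9d replicate 1 with 4 (adjusted p = 0.070). Glycolysis genes did so with 10 and 8 of 20 in wild_type and 9 in yaf9d replicate 2 (Fisher's exact test, adjusted p = 0.00049, 0.0051 and 0.0042), and not in yaf9d replicate 1 with 2 (adjusted p = 0.72). Outside the outermost 1 kb, a peak on the left arm of chromosome XIII from 5326 to 5783 had folds of 6.23, 5.52, 7.57 and 5.84.

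Of the tests below, the one on the background of heat shock genes was set before its result was seen, and the others after.

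The higher number of tRNA genes under peaks in yaf9d was set against the length of the lists, their sensitivity and the genotype. With 616 peaks in each library the difference was 37.5 genes, against a pooled SD between replicates of 8.94 in the full lists, which argues against list length. Higher sensitivity of the yaf9d libraries stays open: coding promoters with a peak differed by -161 genes in the full lists (905.5 to 744.5), by 36 at a fold of 2 or more (438 to 474), and by -80, -145.5, -18.5 and -127 with a stricter q, equal numbers of peaks, summit windows and longer promoters. They were thus fewer in yaf9d in 5 of 6 settings, and each yaf9d library was below each wild_type library in 2. The deletion of YAF9 stays open as untested, since the exact permutation p of 0.333 is the smallest 2 libraries against 2 can give and decides nothing. Reads shared between tRNA copies stay open too without the reads.

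Peaks over highly transcribed genes with a high background may reflect broad signal at such genes. Of peaks inside glycolysis genes 0 of 27 reached a fold of 2, and 23 stood on a background over 3 times the library median. The sources used here do not say whether a control was used, so signal at highly transcribed genes in the control as well cannot be told apart from broad signal of the immunoprecipitate itself. A high background does not account for peaks with their summit in a ribosomal protein promoter. There the highest of the 4 background ratios was 0.775. Whether signal not due to tagged Swc4 lies at these promoters was not tested, since all 4 libraries carried the tag. Part of the peaks inside ribosomal protein genes had a high background (32 of 53, 25 of 61, 16 of 18 and 27 of 57 over 3 times the library median). For peaks overlapping heat shock and chaperone genes in yaf9d the higher ratio was 2.23, below the bound of 3. Only 2 of 8 and 3 of 13 of these peaks reached a fold of 2, so transcription-linked background and Swc4 binding cannot be told apart for the group. The HSP42 peaks stood on 0.793 and 0.752 times the library median, without a high background.

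The peaks beside YAF9 in both yaf9d libraries may be the edge of the deleted gene. Their first base lay 1 bp beyond the coding sequence in each, and no wild_type library had a peak within 1 kb, so the pattern also fits the genotype given in the titles. Binding of tagged Swc4 at the inserted marker cannot be told apart from this, because 0 marker sequences appear among the sequences of the peak lists.

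The split by genotype gave 224 differing loci and was the highest, 1 of 3 splits reaching that number, with 75 as the highest of the others. The 3 splits are too few for a share under 0.05.

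A hypothesis drawn from the named loci was that wild_type loci not called in yaf9d include promoters of ribosome assembly genes. Among 56 genes named UTP, RRP, NOP or NOC with a number, 4 (RRP7, UTP9, UTP25 and RRP40) lay under such loci, 7.14% against 2.98% of other genes (Fisher's exact p = 0.0876), which does not pass. RRP7 and UTP9 had prompted the hypothesis. The ribosome biogenesis list, fixed in advance, had 0 of 27 members there against 3.03% of other genes (exact p = 1). Under loci called in yaf9d alone the number was 0 of 56 against 1.46% of other genes (exact p = 1), which is no contrast. By library, 14.3% and 19.6% of the 56 had a promoter peak in wild_type against 15.9% and 14.3% of other genes, and 1.79% and 5.36% in yaf9d against 11.3% and 13.6% (Fisher's exact p = 0.86, 0.25, 0.018 and 0.077, not adjusted).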
